A study of Homo sapiens with 14 samples.

How the data were processed

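Poly(A) RNA was sequenced from HEK293T cells, a human embryonic kidney line, that stably expressed the peroxidase APEX2 fused to PCNT and EGFP (at the centrosome) or to a nuclear export signal, NES (in the cytosol). Per the labels' protocols, cells were given s6G (6-thioguanosine) for 5 h, then 0.5 mM biotin-phenol probe for 30 min, and labelling was started with 1 mM hydrogen peroxide for 1 min. One field of the labels gives the s6G dose as 100 µM and another gives it as 100 mM, so the dose is uncertain. Part of the purified RNA was kept as Input, and the rest went through affinity purification, which gave Enrich libraries, or Control libraries where the probe had been left out. Libraries were made with a poly(A) selection module and the NEBNext Ultra II RNA kit, per the labels' protocols.

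The authors deposited a table of raw counts per gene for 14 libraries, with 57992 genes and 5 summary lines that name no gene. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.6.1 and the human build GRCh38 (hg38) were used. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies (7SL, histone and ribosomal protein genes, BCYRN1) could therefore be counted together or lost, and values of such genes are uncertain. The summary lines stayed out of library sizes and tests. Their shares of all records were as follows for reads in no gene, reads in more than 1 gene, reads of low quality, unaligned reads and reads with no unique alignment. In NES_Enrich these were 6.48%, 5.89%, 2.85%, 4.18% and 28.5% on average, and in NES_Input 4.21%, 7.63%, 2.47%, 2.88% and 20.3%. In PCNT_Enrich they were 5.73%, 6.02%, 2.38%, 6.08% and 13.9%, in PCNT_Input 7.99%, 6.95%, 2.38%, 2.36% and 17.1%, and in PCNT_Control 11.0%, 6.76%, 2.13%, 7.96% and 16.6%.

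Libraries were grouped by the labels into PCNT_Input (n = 3), PCNT_Enrich (n = 3), PCNT_Control (n = 2, replicates 2 and 3), NES_Input (n = 3) and NES_Enrich (n = 3). A PCNT_Control replicate 1 was not analysed here. The labels call the replicates biological, without saying what separated them, and name no library batch or sequencing date, so differences between the lines cannot be told apart from separate handling of the lines. No pair of replicates agreed within sampling noise (chi-square per gene from 3.09 to 88.9), so each library counted as 1 replicate.

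Counts were tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test (robust fit, TMM scaling, the edgeR expression filter, two-sided), with Benjamini-Hochberg adjustment over all genes tested. These p-values measure the spread between the replicates of a line, not between independent lines. A gene was called at an adjusted p below 0.05, and a gene described as higher or lower without further words was called. Centrosome enrichment was PCNT_Enrich minus PCNT_Input, cytosol enrichment was NES_Enrich minus NES_Input, centrosome against cytosol was the difference between those (an interaction), and input against input was PCNT_Input minus NES_Input. These shared a fit of 12 libraries and 4 groups, with 16030 genes tested, 8 residual degrees of freedom and a common biological coefficient of variation of 19.7%. Probe against no probe was PCNT_Enrich minus PCNT_Control in a fit of those 5 libraries alone, with 14883 genes tested, 3 residual degrees of freedom and a coefficient of variation of 41.8%. The centrosome set held the genes called higher in centrosome enrichment, in centrosome against cytosol and in probe against no probe. Values after ± are standard errors (SE) for log2 fold changes and standard deviations (SD) for levels in CPM (counts scaled to library size). The SE was derived as the absolute log2 fold change divided by the square root of the test's F statistic. It is approximate, above all for genes with few counts.

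A total of 13 gene lists were fixed from general knowledge: imaged centrosomal mRNAs, centrosome and centriole proteins, mitotic spindle and kinetochore genes, dynein and dynactin with their adaptors, ER and secreted proteins, mitochondrially encoded mRNAs, nuclear-retained long noncoding RNAs, cytosolic ribosomal proteins, nuclear-encoded OXPHOS subunits, ZNF genes, immediate-early and stress mRNAs, glycolysis and translation elongation, and blood, liver and fibroblast markers. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. Members called were counted over all genes and adjusted over the list alone. Lists are described as called by camera with the preset correlation. With the estimated correlation, glycolysis and translation elongation in input against input was the only list of any comparison to keep its call. Fry called lists that camera did not, such as dynein genes in cytosol enrichment (adjusted p = 0.000757) and in centrosome against cytosol (0.00711). It did not call others that camera called, such as mitochondrially encoded mRNAs in centrosome enrichment (0.0726).

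The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took PCNT, DLGAP5 and the imaged mRNAs; the 8 largest called changes in each direction (5 for probe against no probe and input against input) among genes with a mean of at least 50 counts, no overlap between the groups and a name that is not a clone or pseudogene; up to 3 called members of each list with the smallest p; and the 10 members of the centrosome set with the largest difference between lines. DLGAP5 is in the title of the series, so it is not independent evidence. Genes were matched by Ensembl identifier, and coordinates are those of GENCODE release 29 on GRCh38; 57388 of the 57992 identifiers were in that release.

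Alternatives were other scalings (DESeq2 size factors, total count), other filters (any count; CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, a minimum fold of 1.5 (glmTreat), other sets of libraries in the fit, a replicate block, and each library left out in turn. A correction for GC share and transcript length, alone and with the block, was added after seeing the data; 99.7% of tested genes had both values. Tests of the lists that hold PCNT were also repeated without it, likewise after seeing the data. Per the labels' protocols each biological replicate gave its own Input, Enrich and Control, so equal numbers pair libraries within a line. Deviations from the group means of same-numbered Input and Enrich libraries correlated across genes at 0.033, 0.0977 and 0.147 in the PCNT line and at 0.202, 0.286 and 0.0143 in the NES line. For Control and Enrich, the values were 0.00265 and 0.0663. Numbers do not pair the lines with each other. The replicate block of input against input used them all the same, so it stands there for no known pairing.

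The fit was tested on simulated counts with 200 changed genes per comparison. For 2-fold changes it called 50.7% in centrosome enrichment, 58.2% in cytosol enrichment, 13.4% in centrosome against cytosol, 47.8% in input against input and 2.99% in probe against no probe; for 4-fold changes it called 86.4%, 81.8%, 71.2%, 75.8% and 53%. False calls numbered 1 to 5 per comparison. The real comparisons called 3772 to 10205 genes, far more than were changed here, so the shares recovered in the data can differ. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Shares of single libraries carry 95% Wilson intervals, which cover counting error only, as do floors of 3 counts per library for genes without counts; sequenced copies are not independent molecules.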

Results

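RNA near the centrosome and in the cytosol of HEK293T cells was profiled by MERR APEX-seq, a form of proximity labelling. APEX2 is an engineered peroxidase that, given hydrogen peroxide, turns biotin-phenol into a short-lived radical that tags nearby RNA with biotin. The nucleoside s6G, given beforehand, is built into newly made RNA and reacts readily with the radical. Counts per gene were given for 14 libraries. Total counts in genes were 9901112, 9822974 and 9533874 in PCNT_Input, 10160368, 5770457 and 10169194 in PCNT_Enrich, and 6770197 and 7740473 in PCNT_Control replicates 2 and 3. They were 10033870, 10021132 and 9111392 in NES_Input and 11801789, 11250919 and 12761694 in NES_Enrich. A floor of 3 counts corresponded to 0.235 to 0.52 CPM, depending on the library.

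Mitochondrially encoded RNA, made in the matrix, behind membranes that the phenoxyl radical hardly crosses, was followed across the libraries. It took 6.92% ± 0.10 (SD, n = 3) of counts in NES_Input and 0.691% ± 0.104 (SD, n = 3) in NES_Enrich, with no overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). In the PCNT line it took 4.65% ± 0.247 (SD, n = 3) in PCNT_Input and 2.68% ± 1.84 (SD, n = 3) in PCNT_Enrich (exact permutation test, two-sided, p = 0.3). The PCNT_Enrich libraries lay far apart, at 0.999% (95% Wilson interval 0.993 to 1.01), 2.4% (2.39 to 2.42) and 4.64% (4.63 to 4.65) in replicates 1, 2 and 3. PCNT_Control libraries held 4.47% (4.45 to 4.48) and 6.58% (6.56 to 6.59), against which PCNT_Enrich gave an exact two-sided permutation p of 0.4, where 0.2 is the smallest that 3 against 2 allows.

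**Figure D1:**
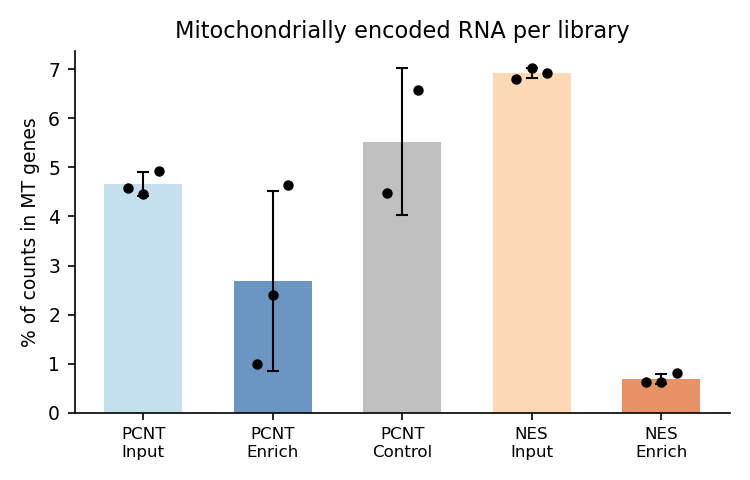
Percentage of counts in mitochondrially encoded (MT) genes, per library (points), with the mean (bars) and SD (error bars) of each group. NES_Enrich libraries lie between 0.627% and 0.811%, and PCNT_Enrich libraries between 0.999% and 4.64%.

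Centrosome enrichment set the pulldown of the line with APEX2 at the centrosome against its Input. It can therefore also hold RNA that was pulled down without being tagged. PCNT, the pericentrin gene that also forms part of the APEX2 fusion (chromosome 21, 46324122 to 46445769, plus strand), was 3.42 ± 0.21 higher on the log2 scale in PCNT_Enrich than in PCNT_Input (3465 ± 1148 CPM against 328 ± 34.5 CPM, SD, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.13e-08). Counts of the fusion and of the endogenous gene could not be separated. Among other rises were those of ANKRD1, a target of YAP signalling (3.36 ± 0.40), DUSP5, a phosphatase that inactivates ERK (3.06 ± 0.37), and KCNJ12, a potassium channel (3.03 ± 0.39). Further rises were in SGK1, a kinase induced by serum and glucocorticoids (2.98 ± 0.30), SERTAD1, a cell cycle regulator (2.87 ± 0.33), and PLK2, a polo-like kinase (2.86 ± 0.36). DLGAP5, which encodes the spindle protein HURP (chromosome 14, 55148112 to 55191678, minus strand), was not called, at 0.18 ± 0.16 (78.2 ± 4.84 against 69.7 ± 5.92 CPM, SD, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.372). Falls were seen in RN7SL2 (−6.07 ± 0.63) and Metazoa_SRP.109 (−6.04 ± 0.75), genes of the 7SL RNA family of the signal recognition particle with near-identical copies, and in MT-TP (−2.75 ± 0.28), a mitochondrial tRNA. Lower too were CORO6 (−2.51 ± 0.31), a coronin, and HSPG2 (−2.46 ± 0.28), which encodes the matrix proteoglycan perlecan. In all, 4214 of 16030 genes were higher and 3181 were lower, of which 2273 and 1529 changed by at least 2-fold.

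Of the 8 imaged centrosomal mRNAs, 4 were higher: PCNT, BICD2, a dynein adaptor (2.25 ± 0.18), NIN, ninein (1.16 ± 0.20), and CEP350, a centriole protein (1.02 ± 0.24). The others, HMMR (0.19 ± 0.18), CCDC88C (0.09 ± 0.21), ASPM (−0.29 ± 0.18) and NUMA1 (−0.32 ± 0.18), were not called, although NUMA1 was called without PCNT_Enrich replicate 1 (−0.60, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00216). ASPM was called lower with the GC and length correction (−0.63, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00026; 0.000432 with the block as well). The list median was 0.61 (camera, Benjamini-Hochberg adjusted p = 0.00201; adjusted p = 0.368 with an estimated correlation). Without PCNT, whose counts include the transgene, the median was 0.19 and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.0691). Among 61 centrosome and centriole proteins 14 were higher and 16 lower, with CCDC14 at −1.92 ± 0.22 and TUBGCP2, of the gamma-tubulin ring complex, at −1.37 ± 0.17 (list median −0.09; camera, Benjamini-Hochberg adjusted p = 0.297). Mitotic spindle and kinetochore genes were higher in 26 and lower in 3 of 59, with FAM83D at 1.69 ± 0.19, CKAP2L at 1.31 ± 0.19 and the centromeric histone CENPA at 1.09 ± 0.17 (median 0.29; camera, Benjamini-Hochberg adjusted p = 0.0132; adjusted p = 0.475 with an estimated correlation), with a median of 0.14 after the GC and length correction. Of 30 dynein and dynactin genes 7 were higher and 5 lower, with DCTN1 at −1.26 ± 0.14. Median and mean were both 0.04 and fry pointed up, whereas camera pointed down (Benjamini-Hochberg adjusted p = 0.856) and the median turned to −0.19 with the GC and length correction.

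Immediate-early and stress mRNAs, which are short-lived, rose in 33 of 37 cases, with DNAJB1, an HSP40 chaperone, at 2.42 ± 0.22, GADD45B at 2.28 ± 0.21 and JUND at 1.84 ± 0.17 (median 1.44; camera, Benjamini-Hochberg adjusted p = 9.95e-17; adjusted p = 0.322 with an estimated correlation). ZNF genes, a large family of zinc finger transcription factors, were higher in 260 and lower in 16 of 427, with ZNF649 at 2.05 ± 0.20 (median 0.85; camera, Benjamini-Hochberg adjusted p = 3.64e-13; adjusted p = 0.368 with an estimated correlation). Ribosomal protein mRNAs fell in 62 of 82 and rose in 1, RPL7L1, a ribosome biogenesis factor despite its name (1.07 ± 0.17). RPL3 stood at −1.43 ± 0.17 (list median −0.99; camera, Benjamini-Hochberg adjusted p = 2.56e-14; adjusted p = 0.368 with an estimated correlation). Lower members outnumbered higher ones in OXPHOS subunits (38 against 2 of 81, median −0.59, NDUFV1 at −1.65 ± 0.20), ER and secreted proteins (27 against 9 of 56, median −0.40, laminin gene LAMB1 at −1.80 ± 0.23) and glycolysis and elongation (14 against 1 of 24, median −0.77). The member that rose there was HSPA8, the HSC70 chaperone (2.43 ± 0.20). Camera gave Benjamini-Hochberg adjusted p of 2.55e-07, 0.000678 and 0.000418 for these, and adjusted p of 0.472, 0.368 and 0.368 with an estimated correlation.

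Of 13 mitochondrially encoded mRNAs 8 were lower (median −0.83; camera, Benjamini-Hochberg adjusted p = 0.00409; adjusted p = 0.475 with an estimated correlation), with MT-CO3 at −1.18 ± 0.34. That value was −0.77 without PCNT_Enrich replicate 1 and −1.80 without PCNT_Enrich replicate 3. Its call was lost when the PCNT line was fitted alone (−1.27, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0512), with all genes with any count (−1.25, 0.074) and with a minimum fold of 1.5 (0.0644). In the list of nuclear-retained noncoding RNAs 5 of 13 were lower and 1 was higher. MALAT1, a nuclear speckle RNA, stood at −2.44 ± 0.20 and OIP5-AS1 at 0.90 ± 0.19. Whether each member stays in the nucleus of these cells was not tested. The list median was −0.37 (camera, Benjamini-Hochberg adjusted p = 0.0378, and 0.368 with an estimated correlation), and −0.58 after the GC and length correction. Of the blood, liver and fibroblast markers only 4 were tested, too few for a list test, and COL1A1 was lower (−1.35 ± 0.25). Adjusted over the list alone, the counts differed only for ER and secreted proteins (9 higher, 28 lower), ribosomal proteins (1 and 63), ZNF genes (274 and 17) and glycolysis and elongation (1 and 15). PCNT_Enrich replicate 3, whose mitochondrial share was that of Input, did not decide the totals: without it 5075 genes were higher and 4042 lower.

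**Figure D2:**
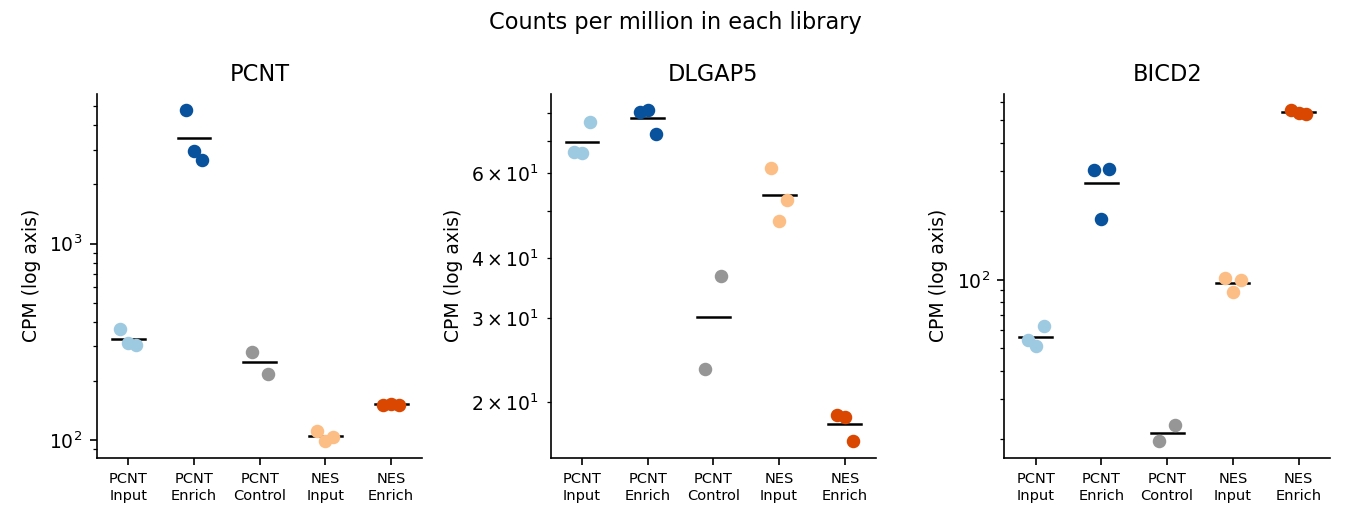
CPM (log axis) of PCNT, DLGAP5 and BICD2 in each library (points) by group, with group means (lines). PCNT averages 3465 CPM in PCNT_Enrich and 249 CPM in PCNT_Control, and DLGAP5 averages 78.2 CPM in PCNT_Enrich and 18 CPM in NES_Enrich.

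Cytosol enrichment gave the reference compartment. DLGAP5 was lower in NES_Enrich than in NES_Input by −1.87 ± 0.16 on the log2 scale (18 ± 1.21 against 54 ± 6.99 CPM, SD, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.22e-08). PCNT, at 0.25 ± 0.19, was not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.262), though it was with total-count scaling (0.55, adjusted p = 0.0197) and in the NES libraries fitted alone (0.23, adjusted p = 0.0394). Histone genes led the rises, among them HIST1H1E, a linker histone (7.80 ± 0.44), HIST1H2AH (5.55 ± 0.49) and HIST2H2BF (5.52 ± 0.50), genes whose near-identical copies make single values uncertain. Mitochondrially encoded mRNAs led the falls, with MT-ND3 at −4.42 ± 0.39, MT-CO1 at −4.35 ± 0.35 and MT-CO2 at −4.23 ± 0.37. Higher genes numbered 5274 and lower genes 4931 of 16030, with 3748 and 3687 changed by at least 2-fold. The share of higher among called genes was 51.7%, and 61.7% with total-count scaling, which shifted genes by a median of 0.29.

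All 13 mitochondrially encoded mRNAs fell (median −4.17; camera, Benjamini-Hochberg adjusted p = 1.39e-09; adjusted p = 0.202 with an estimated correlation). Ribosomal protein mRNAs fell in 80 and rose in 1 of 82, with RPL3 at −2.79 ± 0.18 (median −2.74; camera, Benjamini-Hochberg adjusted p = 1.28e-32; adjusted p = 0.202 with an estimated correlation). OXPHOS subunits fell in 69 and rose in 2 of 81, with COX5A at −3.18 ± 0.21 (median −2.34; camera, Benjamini-Hochberg adjusted p = 1.84e-24; adjusted p = 0.202 with an estimated correlation). Glycolysis and elongation genes fell in 22 and rose in 1 of 24 (median −1.76), and ER and secreted proteins fell in 37 and rose in 10 of 56 (median −0.97). Camera gave Benjamini-Hochberg adjusted p of 1.39e-09 and 2.06e-06, and adjusted p of 0.105 and 0.202 with an estimated correlation. PABPC1, the poly(A)-binding protein, stood at −2.68 ± 0.17 and LAMB1 at −3.17 ± 0.23. ZNF genes were higher in 358 and lower in 11 of 427, with ZNF292 at 3.17 ± 0.23 (median 1.67, or 1.65 with 5 genes set at their count floor; camera, Benjamini-Hochberg adjusted p = 2.52e-24; adjusted p = 0.202 with an estimated correlation). Immediate-early mRNAs rose in 31 of 37, with DDIT4, an inhibitor of mTORC1, at 2.33 ± 0.21 and KLF10 at 1.91 ± 0.19 (median 1.29; camera, Benjamini-Hochberg adjusted p = 6.29e-07; adjusted p = 0.226 with an estimated correlation).

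Of the imaged mRNAs in the cytosol, BICD2 (2.20 ± 0.18), CEP350 (2.00 ± 0.25), CCDC88C (0.86 ± 0.22) and NUMA1 (0.41 ± 0.18) were higher and HMMR was lower (−1.26 ± 0.19). ASPM (0.33 ± 0.19) was not called, but it was called higher with total-count scaling (0.62, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00778) and lower with the GC and length correction (−0.33, adjusted p = 0.0191; 0.0212 with the block as well). The NUMA1 call (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0495) was lost when any of the 6 NES libraries was left out, with adjusted p from 0.0675 to 0.152. NIN, at 0.34 ± 0.20 and not called, passed with the replicate block (0.34, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0443) and with total-count scaling (0.62, adjusted p = 0.0143). The lists of imaged mRNAs (median 0.38), centrosome proteins (24 higher, 19 lower of 61, median 0.34), spindle genes (21 and 15 of 59, median 0.30), dynein genes (11 and 15 of 30, median −0.43) and nuclear noncoding RNAs (1 and 5 of 13, median −0.37) were not called (camera, Benjamini-Hochberg adjusted p from 0.179 to 0.706). The medians of imaged mRNAs and centrosome proteins turned to −0.03 and −0.07 with the GC and length correction, and that of spindle genes was 0.05. With total-count scaling the medians were 0.66 for imaged mRNAs, 0.62 for centrosome proteins, 0.59 for spindle genes, −0.14 for dynein genes and −0.09 for nuclear noncoding RNAs. Among the fibroblast and blood markers 3 of 4 were lower, with COL1A1 at −2.59 ± 0.24. Adjusted over the list alone, counts moved by at most 2 genes in either direction in any list, to 360 higher and 13 lower for ZNF genes and 10 and 39 for ER and secreted proteins.

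**Figure D3:**
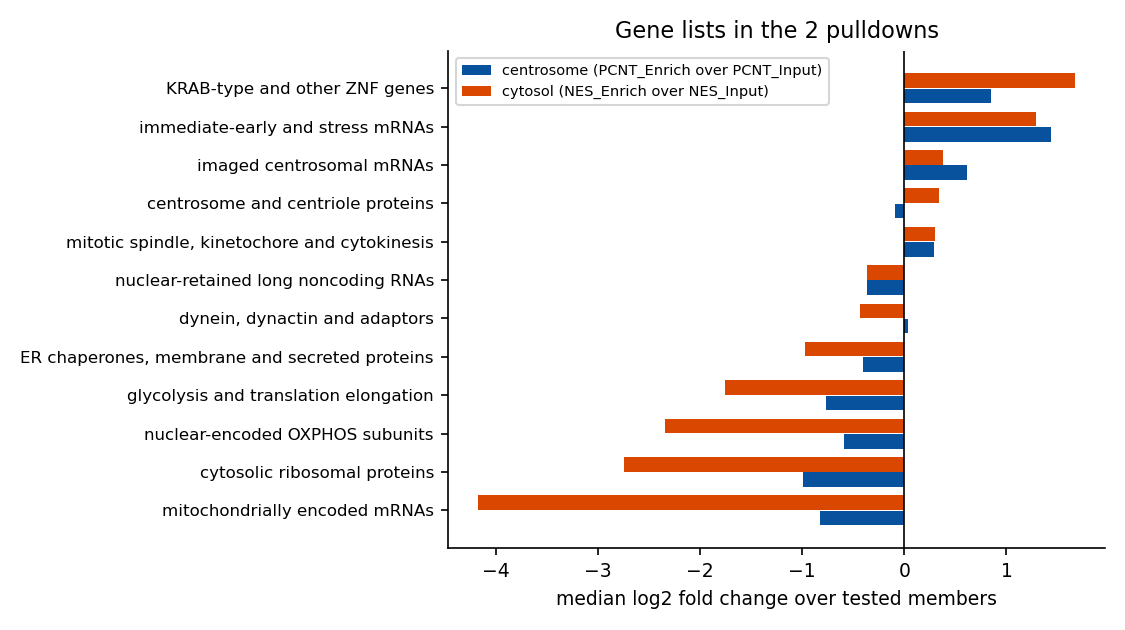
Median log2 fold change of the tested members of 12 gene lists in centrosome enrichment (blue) and cytosol enrichment (orange). Medians of mitochondrially encoded mRNAs are −0.83 and −4.17; those of imaged centrosomal mRNAs and of centrosome and centriole proteins in the cytosol, and of dynein genes at the centrosome, turn below 0 with the GC and length correction.

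Fold changes of both enrichments correlated across 16030 genes (Pearson 0.58, Spearman 0.65; genes are not independent replicates), with SDs of 0.99 at the centrosome and 1.42 in the cytosol. Genes higher in both numbered 3259, against 1386 for independent lists, and genes lower in both numbered 2289, against 978.5; the enrichments share no library. Opposite calls were few, with 183 genes higher at the centrosome and lower in the cytosol and 105 the other way.

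**Figure D4:**
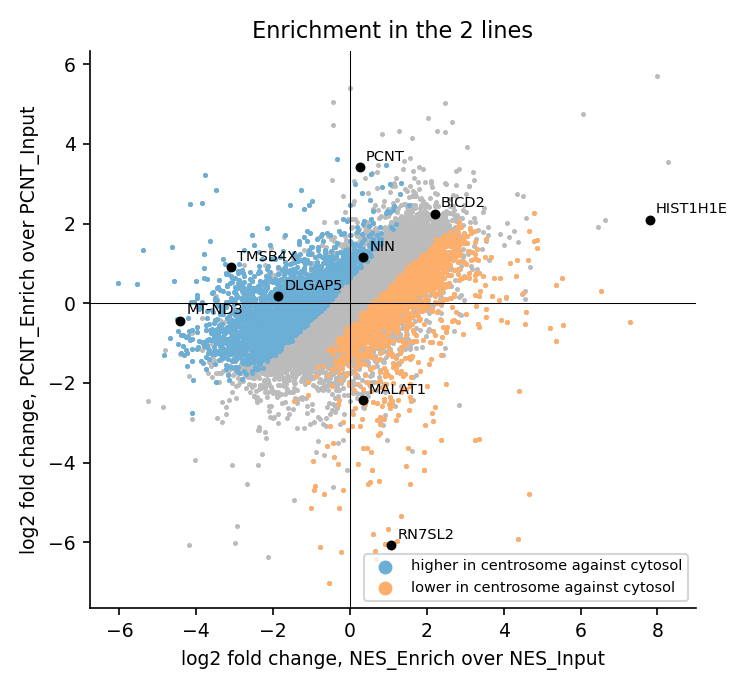
Log2 fold change of each gene in centrosome enrichment (y axis) against cytosol enrichment (x axis), with genes called in the difference in blue (2867 higher) and orange (1951 lower). PCNT lies at 3.42 and 0.25, DLGAP5 at 0.18 and −1.87, and BICD2 at 2.25 and 2.20.

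Centrosome against cytosol tested the difference of the enrichments itself. PCNT had the larger enrichment at the centrosome by 3.17 ± 0.28 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.31e-06). DLGAP5 differed by 2.05 ± 0.23 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.45e-05), from a value near 0 at the centrosome and a fall in the cytosol, and was called in all 23 alternatives, between 1.75 and 2.15. HMMR, which encodes a spindle-binding hyaluronan receptor (chromosome 5, 163460203 to 163491945), followed at 1.46 ± 0.26, with values of 0.19 and −1.26 in the enrichments. BICD2 was higher in both enrichments, and its difference of 0.05 ± 0.25 was not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.896). The difference rose to 0.40 and was called with the block and the GC and length correction (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0428). It was −1.19 with Enrich libraries only, which leaves the lines' Input difference in. Positive differences included those of EMP3, a membrane protein (5.21 ± 0.97), NPC2, a lysosomal cholesterol carrier (4.41 ± 0.40), TMSB4X, thymosin beta-4 (4.01 ± 0.28), and ATP5G1, an ATP synthase subunit (3.97 ± 0.50). EMP3, NPC2 and ATP5G1 were more abundant in PCNT_Control (68.1, 217 and 397 CPM) than in PCNT_Enrich (22.5, 67.8 and 149 CPM). Negative differences included those of 7SL genes (RN7SL2, −7.14 ± 0.79), HIST1H1E (−5.70 ± 0.71) and HIST2H2BF (−4.89 ± 0.77).

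Higher differences were called in 2867 genes and lower ones in 1951. Of the 2867, 497 were also higher in centrosome enrichment, 1495 were not called there, 875 were lower there and 2521 were lower in cytosol enrichment, with median fold changes of −0.19 and −1.69. Of the 1951, 1601 were higher in cytosol enrichment and 671 in both. Total-count scaling shifted genes by a median of −0.31 and moved the share of higher among called genes from 59.5% to 35.4%. NIN (0.82 ± 0.28), CEP350 (−0.98 ± 0.34) and NUMA1 (−0.73 ± 0.25) were called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.031, 0.0335 and 0.034). NIN lost its call without NES_Enrich replicate 2 or 3, NES_Input 1 or 3, PCNT_Enrich 1 or PCNT_Input 3 (adjusted p from 0.055 to 0.0968, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). CEP350 reversed to 0.85 with Enrich libraries only (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0047). It lost its call with the GC and length correction (−0.54, adjusted p = 0.0614), as NUMA1 did (−0.33, 0.118). CEP350 also lost it without NES_Enrich 1 or 3, NES_Input 2 or 3, PCNT_Enrich 2 or PCNT_Input 1 or 3 (0.0511 to 0.106). NUMA1 lost it without any of 8 libraries (NES_Enrich 2 or 3, NES_Input 1, 2 or 3, PCNT_Enrich 2, PCNT_Input 1 or 3; 0.0617 to 0.0785). CCDC88C (−0.76 ± 0.30, not called) passed with the replicate block (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0384), DESeq2 size factors (0.0432), the DESeq2 test (0.0284) and total-count scaling (0.0128), and without NES_Enrich replicate 2 (0.0455), PCNT_Enrich 1 (0.0494) or PCNT_Enrich 3 (0.0363). ASPM (−0.62 ± 0.26, not called) passed with DESeq2 size factors (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0477), the DESeq2 test (0.0383) and total-count scaling (0.0123), and without PCNT_Enrich replicate 1 (0.0362). It reversed to 0.95 with Enrich libraries only (adjusted p = 0.000307, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

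Mitochondrially encoded mRNAs were higher in this difference in 12 of 13, with MT-ND3 at 3.98 ± 0.50 (median 3.07; camera, Benjamini-Hochberg adjusted p = 2.19e-12; adjusted p = 0.266 with an estimated correlation). Ribosomal protein mRNAs were higher in 75 of 82, with RPS29 at 4.23 ± 0.65 (median 1.82; camera, Benjamini-Hochberg adjusted p = 1.94e-27; adjusted p = 0.266 with an estimated correlation). The same direction held for OXPHOS subunits (68 higher and 1 lower of 81, median 1.76), glycolysis and elongation (18 of 24 higher, median 1.00) and ER and secreted proteins (25 higher and 2 lower of 56, median 0.58). Camera gave Benjamini-Hochberg adjusted p of 1.29e-25, 4.95e-08 and 0.000403, and adjusted p of 0.266, 0.146 and 0.373 with an estimated correlation. The median of ER and secreted proteins was 0.27 with total-count scaling. All these lists had negative medians in both enrichments, where their calls too were lost with an estimated correlation. The mitochondrial share of PCNT_Enrich ran from 0.999% to 4.64%, against 0.691% ± 0.104 (SD, n = 3) in NES_Enrich. ZNF genes were lower in 158 and higher in 5 of 427 (median −0.75, or −0.74 with 5 genes at their floor; camera, Benjamini-Hochberg adjusted p = 6.73e-16; adjusted p = 0.266 with an estimated correlation). Among 13 nuclear noncoding RNAs 1 was higher, JPX (0.78 ± 0.26), and 1 lower, MALAT1 (−2.77 ± 0.28). The JPX call (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0283) held in 12 of 23 alternatives, and it was lost without NES_Enrich replicate 1 or 3, NES_Input 1 or 3, PCNT_Enrich 2 or PCNT_Input 1, 2 or 3 (adjusted p from 0.0507 to 0.0889). The list had a median of −0.22, and of 0.16 with the GC and length correction (camera, Benjamini-Hochberg adjusted p = 0.23).

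Lists named for the centrosome and spindle were not called in the difference (camera, Benjamini-Hochberg adjusted p from 0.202 to 0.397). The imaged mRNAs had a median of −0.28, a mean of 0.30 and a test pointing up, with a median of 0.06 after the GC and length correction. Without PCNT their median was −0.62 and the test pointed down (camera, Benjamini-Hochberg adjusted p = 0.615). Centrosome proteins were higher in 6 and lower in 9 of 61, CETN2, a centrin, at 1.69 ± 0.27 and AKAP9, a scaffold protein, at −1.58 ± 0.26. AKAP9 reversed to 0.95 with Enrich libraries only. Spindle genes were higher in 15 and lower in 6 of 59, with BUB1, a checkpoint kinase, at 1.40 ± 0.24. Dynein genes were higher in 10 and lower in 5 of 30, with ACTR10, of dynactin, at 1.84 ± 0.27. The medians of spindle and dynein genes, both 0.15, turned to −0.16 with total-count scaling. Immediate-early mRNAs were higher in 5 and lower in 2 of 37 (camera, Benjamini-Hochberg adjusted p = 0.431), and 2 of 4 tested blood and fibroblast markers were higher. Adjusted over the list alone, imaged mRNAs had 3 higher and 4 lower members, mitochondrially encoded mRNAs 13 higher, ribosomal proteins 78 higher and ZNF genes 6 higher and 166 lower; counts of other lists moved by at most 2 genes in either direction.

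Probe against no probe set PCNT_Enrich against the pulldown without biotin-phenol. PCNT was 3.65 ± 0.41 higher with the probe (3465 ± 1148 CPM, n = 3, against 249 ± 46.7 CPM, n = 2, SD; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00102). BICD2 (3.48 ± 0.35), NIN (2.88 ± 0.32) and CEP350 (1.44 ± 0.29) were higher too. DLGAP5 was higher by 1.22 ± 0.34 (78.2 ± 4.84 CPM, n = 3, against 30.1 ± 9.34 CPM, n = 2, SD; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0217). Its call was lost without PCNT_Control replicate 2 (0.90, adjusted p = 0.122), PCNT_Enrich replicate 1 (1.22, 0.0719) or PCNT_Enrich replicate 2 (1.19, 0.0956; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and with the GC and length correction (0.52, 0.201). ASPM (1.37 ± 0.34) lost its call without the same libraries (adjusted p 0.0815, 0.0546 and 0.0708, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and with the correction (0.49, 0.253). HMMR (0.47 ± 0.29), CCDC88C (0.55 ± 0.42) and NUMA1 (−0.11 ± 0.32) were not called. Genes without counts in either Control library included SOX2, a transcription factor of neural and stem cells (16.5 ± 4.25 CPM in PCNT_Enrich, SD, n = 3, at least 39.7-fold higher than a floor of 3 counts per library), ZNF701 (at least 35.7-fold) and AKAP5 (at least 27.8-fold). Control replicates 2 and 3 also lacked counts of 22 and 49 genes well counted in PCNT_Input, which PCNT_Enrich libraries did not. Zeros in Control may thus be genes lost from these libraries, and the folds are bounds on counting error only. AOC3, an amine oxidase (−4.01 ± 0.63), and ADAM8, a metalloprotease (−3.46 ± 0.60), were lower.

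Among 14883 genes 2104 were higher and 1668 lower with the probe. Without PCNT_Enrich replicate 2 these counts were 744 and 399, and without PCNT_Enrich replicate 1 they were 1109 and 722. The share of higher among called genes was 55.8%, and 41.9% with the GC and length correction (64.9% with total-count scaling, which shifted genes by a median of 0.14). Immediate-early mRNAs rose in 22 and fell in 1 of 37, with KLF6 at 2.83 ± 0.41 (median 1.52; camera, Benjamini-Hochberg adjusted p = 8.88e-09; adjusted p = 0.377 with an estimated correlation). ZNF genes rose in 116 and fell in 12 of 423, with ZNF92 at 3.18 ± 0.37 (median 0.90; camera, Benjamini-Hochberg adjusted p = 4.12e-08; adjusted p = 0.443 with an estimated correlation). Spindle genes rose in 24 and fell in 3 of 57, with SGO2, shugoshin 2, at 3.40 ± 0.45 and CENPF at 1.83 ± 0.30 (median 0.58; camera, Benjamini-Hochberg adjusted p = 5.96e-05; adjusted p = 0.377 with an estimated correlation). The imaged mRNAs rose in 5 of 8 (median 1.40; camera, Benjamini-Hochberg adjusted p = 5.13e-06, and 0.000178 without PCNT; adjusted p = 0.262 with an estimated correlation). With the GC and length correction the medians of imaged mRNAs and ZNF genes were 0.83 and 0.53, and with the block added that of spindle genes was 0.38. Centrosome proteins rose in 15 and fell in 2 of 61, with the mitotic kinase gene NEK2 at 2.22 ± 0.34. The list (median 0.28, −0.29 with the GC and length correction) was not called (camera, Benjamini-Hochberg adjusted p = 0.0566) but was with the replicate block (0.0452), not so with an estimated correlation (adjusted p = 0.443; 0.416 with the block).

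Lists called with negative medians in this comparison were ER and secreted proteins (17 lower, 5 higher of 56, −0.47, CTSD at −2.46 ± 0.33), glycolysis and elongation (6 and 1 of 24, −0.57), mitochondrially encoded mRNAs (1 lower of 13, −0.96), ribosomal proteins (4 lower of 82, −0.52) and OXPHOS subunits (12 and 3 of 80, −0.34). Camera gave Benjamini-Hochberg adjusted p of 0.000381, 0.0124, 0.0027, 0.000161 and 0.00292. These adjusted p were 0.443, 0.443, 0.503, 0.597 and 0.597 with an estimated correlation. With the replicate block the medians of mitochondrially encoded mRNAs, ribosomal proteins and OXPHOS subunits were −0.59, −0.27 and −0.16, and with the GC and length correction that of ER and secreted proteins was −0.73. The lower ribosomal protein and mitochondrial calls were lost when adjusted over the list alone. That count gave 131 higher and 14 lower ZNF genes, 25 higher immediate-early mRNAs, 26 higher spindle genes, 16 higher and 3 lower centrosome proteins, 22 lower ER and secreted proteins and 9 lower OXPHOS subunits; others moved by at most 1 gene. Of the blood, liver and fibroblast markers 3 were tested (median −0.98), too few for a list test. Nuclear noncoding RNAs were lower in 5 and higher in 1 of 13 (median −0.98; camera, Benjamini-Hochberg adjusted p = 0.0566). Dynein genes were higher in 6 and lower in 2 of 30 (median 0.12, and −0.17 with the GC and length correction; camera, Benjamini-Hochberg adjusted p = 0.374). With the replicate block, OIP5-AS1 (1.00 ± 0.29) and RPL36A (−1.65 ± 0.40) lost their calls (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0804 and 0.0558).

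The centrosome set of genes higher in centrosome enrichment, in centrosome against cytosol and with the probe held 164 of 14529 genes tested in both fits. Ranked by the difference between lines its first 10 members included NOV, a secreted matrix protein with 1.81 CPM at most in any group mean, CD24, a surface glycoprotein (4.11 ± 0.81), TMSB4X (4.01 ± 0.28), and KRTAP19-1 (3.66 ± 0.72). Also among them were PCNT (3.17 ± 0.28), KRT8, keratin 8 (3.12 ± 0.42), CLCN4, a chloride and proton exchanger (2.86 ± 0.90), and OLFM1, olfactomedin 1 (2.80 ± 0.48). NOV, CLCN4, PROX1-AS1.1 and RP11-722G7.1, all among the first 10, had no counts in either Control library. Their calls with the probe thus rest on zeros, which may be genes lost from those libraries. DLGAP5 was not in the set, because centrosome enrichment did not call it. Of the set, 86 were at least 2-fold higher in PCNT_Enrich than in PCNT_Input, 44 were lower in the cytosol and 28 were higher there. Immediate-early mRNAs had 4 of 36 members in it, SGK1, JUNB, GADD45B and DDIT3 (Fisher's exact test, two-sided, odds ratio 11.2, Benjamini-Hochberg adjusted p = 0.00835 over 12 lists). This list was already higher in 33 of 37 in centrosome enrichment and in 22 of 37 with the probe, which the set requires. In centrosome against cytosol 5 of 37 were higher (camera, Benjamini-Hochberg adjusted p = 0.431), so the overlap does not show a preference for the centrosome over the cytosol. Imaged mRNAs had 2 of 8, PCNT and NIN (odds ratio 29.5, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0203), but PCNT carries the transgene, and without it 1 of 7 remained (Fisher's exact test, p = 0.076). The set also held 3 of 61 centrosome proteins, PCNT, NIN and MZT1 (odds ratio 4.6, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0947).

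Independent lists of the same sizes would share 117.7 genes in the centrosome set. A total of 20 simulated sets of unchanged libraries gave 0 with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 they gave 33 on average. No gene differed between the groups in those sets, whereas 4214, 2867 and 2104 genes were called higher by the 3 criteria. The simulation therefore cannot give the overlap to be expected here. All 3 criteria used the same 3 PCNT_Enrich libraries, which are too few to split between the criteria. Part of the excess may therefore come from the shared libraries. Centrosome enrichment and probe against no probe shared 1734 higher genes, against 604.3 for independent lists, and the excess came from this overlap. Genes with a higher difference between lines were less often higher in centrosome enrichment (17.3%) than genes with a lower difference (34.4%). The set held 52 genes without PCNT_Enrich replicate 2 and 276 without PCNT_Enrich replicate 3.

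Input against input compared the lines before the pulldown. PCNT was 1.19 ± 0.20 higher in PCNT_Input than in NES_Input (328 ± 34.5 against 104 ± 6.18 CPM, SD, n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.26e-05), the direction that the transgene gives. DLGAP5 was not called (−0.09 ± 0.16), though it was with the GC and length correction (−0.47, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00673). EDA2R, a TNF receptor family member (6.72 ± 0.40), ZNF331 (5.72 ± 0.45) and BEX1 (5.59 ± 0.45) were far higher in the PCNT line. CTSZ, a lysosomal protease (−4.92 ± 0.37), LGALS3BP, a secreted galectin-binding protein (−4.53 ± 0.37), and the cytoplasmic actin genes ACTG1 (−3.39 ± 0.24) and ACTB (−2.68 ± 0.21) were lower. Calls covered 3670 higher and 4825 lower genes of 16030, and the share of higher ones moved from 43.2% to 70.6% with total-count scaling, which shifted genes by a median of 0.46 (the GC and length correction shifted genes by a median of 0.14).

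Centrosome proteins were higher in the PCNT line in 41 and lower in 6 of 61, with AKAP9 at 2.53 ± 0.19 and PCM1, of centriolar satellites, at 1.95 ± 0.18 (median 0.95; camera, Benjamini-Hochberg adjusted p = 3.56e-09; adjusted p = 0.137 with an estimated correlation). The imaged mRNAs were higher in 7 of 8 (median 1.22; camera, Benjamini-Hochberg adjusted p = 0.0022; adjusted p = 0.299 with an estimated correlation), BICD2 being lower (−1.25 ± 0.18). NIN (0.84 ± 0.20) was not called with the GC and length correction (0.02). NUMA1 (0.49 ± 0.18) was not called without any 1 of NES_Input 1, 2 and 3 and PCNT_Input 1 and 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p from 0.0605 to 0.0858). All 24 glycolysis and elongation genes were lower, with HSPA8 at −3.35 ± 0.20 (median −1.26; camera, Benjamini-Hochberg adjusted p = 1.93e-13; adjusted p = 0.0307 with an estimated correlation). Ribosomal protein mRNAs were lower in 79 and higher in 1 of 82 and OXPHOS mRNAs lower in 75 of 81 (medians both −1.21; camera, Benjamini-Hochberg adjusted p = 8.9e-13 and 1.93e-13; adjusted p = 0.502 and 0.413 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 10 of 13 (median −1.03), ZNF genes higher in 178 and lower in 67 of 427 (median 0.45) and nuclear noncoding RNAs higher in 6 of 13 (median 0.68). With the GC and length correction the medians were 0.48 for centrosome proteins, 0.72 for imaged mRNAs, 0.21 for ZNF genes, 0.06 for nuclear noncoding RNAs, −0.80 for OXPHOS and −0.83 for glycolysis and elongation. With total-count scaling they were −0.74 for ribosomal proteins and OXPHOS, −0.80 for glycolysis and elongation, −0.56 for mitochondrially encoded mRNAs, 0.91 for ZNF genes and 1.15 for nuclear noncoding RNAs. For mitochondrially encoded mRNAs, ZNF genes and noncoding RNAs camera gave Benjamini-Hochberg adjusted p of 0.0347, 7.51e-05 and 0.00897, and adjusted p of 0.747, 0.686 and 0.299 with an estimated correlation.

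Spindle genes were higher in 27 and lower in 17 of 59 between the Input libraries, with FAM83D at −1.99 ± 0.19. Dynein genes were higher in 11 and lower in 9 of 30, and ER and secreted proteins higher in 14 and lower in 23 of 56. Immediate-early mRNAs were higher in 9 and lower in 15 of 37, with DNAJB1 at −2.42 ± 0.22 and ATF3 at 1.89 ± 0.27. None of these lists was called (camera, Benjamini-Hochberg adjusted p from 0.139 to 0.728). The medians of dynein genes (−0.16, where the camera test pointed up), ER and secreted proteins (−0.24) and immediate-early mRNAs (−0.39) turned to 0.30, 0.22 and 0.07 with total-count scaling, and the last to 0.09 with the GC and length correction. Of 4 tested blood and fibroblast markers 3 were lower, COL1A1 at −2.18 ± 0.24. Adjusted over the list alone, the counts were 41 higher and 7 lower for centrosome proteins, 179 and 67 for ZNF genes, 14 and 25 for ER and secreted proteins, 1 and 76 for OXPHOS subunits, 11 lower for mitochondrially encoded mRNAs and 4 lower for the blood and fibroblast markers, and those of the other lists did not move.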

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

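The tests of separate handling of the lines, of RNA made during the s6G treatment and of other splits of the libraries, and the GC and length corrections, were chosen only after the results were seen. The interaction test of centrosome against cytosol drew attention to 2867 genes with a higher and 1951 with a lower enrichment at the centrosome than in the cytosol. Among imaged mRNAs and DLGAP5 these were PCNT (3.17), DLGAP5 (2.05), HMMR (1.46), NIN (0.82), CEP350 (−0.98) and NUMA1 (−0.73), on the log2 scale; the last 3 lost their calls when single libraries were left out. Other genes with a higher value were EMP3 (5.21), NPC2 (4.41), RPS29 (4.23), BCYRN1 (4.13), TMSB4X (4.01), OST4 (4.0), MT-ND3 (3.98) and ATP5G1 (3.97). Those with a lower value were 7SL genes (RN7SL5P −10.30, RN7SL2 −7.14, Metazoa_SRP.109 −6.96) and histone genes (HIST2H3D −6.31, HIST1H2AH −6.08, HIST1H1E −5.70, HIST1H3B −4.91, HIST2H2BF −4.89), all with near-identical copies, and fitted values of genes with few counts depend on the prior count. List medians of the difference were 3.07 for mitochondrially encoded mRNAs, 1.82 for ribosomal proteins, 1.76 for OXPHOS subunits, 1.00 for glycolysis and elongation, 0.58 for ER and secreted proteins and −0.75 for ZNF genes. All 6 lists lost their calls with an estimated correlation, whereas fry called all 6 (Benjamini-Hochberg adjusted p from 0.0003 to 0.0102). Among records outside the comparisons, those with no unique alignment made up 28.5% ± 1.95 (SD, n = 3) in NES_Enrich and 20.3% ± 0.601 (SD, n = 3) in NES_Input.

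Of the genes with a higher enrichment at the centrosome, 497 (17.3%) were called higher in centrosome enrichment itself, which RNA carried over from Input in proportion cannot give. That share was 34.4% among genes with a lower enrichment at the centrosome, and the difference contains centrosome enrichment, so its size is no support. With the replicate block and the GC and length correction, 92.7% were still called. These values argue against GC share and length as the whole cause. Against carry-over in proportion to Input they argue for the 497 genes only. Of those, 164 were also higher with the probe, and background not in proportion to Input was not tested. Only 83 of these 164 stayed in the centrosome set with the replicate block and the GC and length correction. For the set, GC share and length therefore stay open. For ribosomal protein and mitochondrially encoded mRNAs, carry-over in the centrosome pulldown remains a candidate explanation: an Input-like share estimated from mitochondrial mRNAs (14%, 50.3% and 104% in PCNT_Enrich replicates 1, 2 and 3) predicted the ribosomal protein share with a mean log2 residual of −0.28 (SD 0.19, n = 3). The estimate fails in replicate 3, where no share can pass 100% and PCNT stood at 2659.5 CPM against at most 367.1 CPM in Input. The residual also lies too near its spread to decide, so carry-over and a difference between the compartments cannot be told apart for these mRNAs, and such a difference stays open for the rest.

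Of the gene differences between the Input libraries of the lines, 68.4% stayed called in the same direction with the GC and length correction, which argues against that trend as the whole cause. Separate handling of the lines cannot be told apart from a difference between the lines, since 0 libraries have a batch in their labels. Expression of the transgenes and selection of the lines are biological differences that the design names, and they were not tested.

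Immediate-early and ZNF mRNAs were higher in both pulldowns in 275 members, and 90.9% of these stayed so with the replicate block and the GC and length correction, which argues against GC share and length as the whole cause. A candidate explanation is preferential pulldown of RNA made during the 5 h of s6G, since such mRNAs turn over fast and the list of abundant glycolysis and elongation mRNAs had medians of −0.77 and −1.76 in the enrichments. None of the 14 libraries analysed here lacked s6G, so this stays a hypothesis.

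Splits of 6 libraries into 3 and 3, or for centrosome against cytosol of the 6 pairs of Input and Enrich libraries between the lines, number 10, too few for a share under 0.05; 1 split, the real one, reached the real count each time. Real counts were 7395 genes in centrosome enrichment, 10205 in cytosol enrichment, 4818 in centrosome against cytosol and 8495 in input against input, and the highest count of another split was 0 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Every other split mixes libraries of both real groups in each of its groups, so the real differences add to its spread. Few calls were thus built in, and the 0 does not measure chance. At an unadjusted p below 0.05 the highest other counts were 3014, 320, 297 and 137. Among splits that part all 3 pairs, as the real one does, they were 2574 in centrosome enrichment and 87 in cytosol enrichment; the other splits part 1 pair.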

How the results depend on the processing

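The GC and length corrections and the lists without PCNT were chosen after seeing the data. Of the recomputed counts of genes, 181 stayed within 1.5 times the value in the report, 9 rose beyond it and 16 fell below it. Of gene values, 4724 kept their side of the threshold, 26 gained a call, 135 lost it and 9 reversed. Values that changed sign without a call in either setting counted as kept, such as DLGAP5 in centrosome enrichment (−0.18 to 0.28). Of list tests 89 kept their side of the threshold, 1 gained a call and 40 lost it. A minimum fold of 1.5 left 2134 higher and 1300 lower genes in centrosome enrichment, 1593 and 688 in centrosome against cytosol, 1308 and 828 in probe against no probe, 2082 and 2733 in input against input and 20 in the centrosome set, by its stricter hypothesis. Total-count scaling gave 3530 lower genes in centrosome against cytosol and 6034 higher and 2515 lower in input against input. The centrosome set then held 106 genes (88 shared with the main set). It held 117 (81 shared) with the GC and length correction and 138 (83 shared) with the block as well. A comparison of Enrich libraries only, which leaves the lines' Input difference in, gave 4523 higher genes (1650 shared) and 4359 lower (1256 shared), 603 in the set, and reversed ASPM (0.95), CEP350 (0.85), BICD2 (−1.19), AKAP9 (0.95), FOSB (−0.07) and COL1A1 (−0.95). A fit of all 14 libraries, with more residual degrees of freedom, gave 5042 higher and 3135 lower genes in probe against no probe and 281 in the set. ASPM in the cytosol reversed to −0.33 and was called with the GC and length correction, with and without the block, and OIP5-AS1 with the probe to −0.01 with block and correction. Except where stated, the cause was not tested.

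Leaving out 1 library at a time gave 3501 to 5075 higher and 2591 to 4042 lower genes in centrosome enrichment, 4624 to 4831 and 4525 to 4726 in cytosol enrichment, 2391 to 3220 and 1414 to 2733 in centrosome against cytosol, and 2956 to 3299 and 4027 to 4365 in input against input. For probe against no probe the ranges were 744 (without PCNT_Enrich replicate 2) to 2424 higher and 399 to 1859 lower, with 1109 and 722 without PCNT_Enrich replicate 1; a lone Control library was then assumed to vary like the other group. The set held 52 (without PCNT_Enrich replicate 2) to 276 genes (without PCNT_Enrich replicate 3). The replicate block gave 4315 higher and 3518 lower genes in centrosome enrichment and 1619 and 1121 in probe against no probe. It gave 166 genes in the set (134 shared with the main set). Depth limited genes near 3 counts, 0.235 to 0.52 CPM depending on the library.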

Other observations

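The look at histone genes and at genes lost from the Control libraries was chosen after values were seen. Replication-dependent histone mRNAs lack poly(A) tails, so few were present in poly(A) RNA, yet of 47 histone genes tested 42 were higher in NES_Enrich than in NES_Input (median 3.94). Centrosome enrichment called 17 of them higher (median 1.01), where the share over all genes gives 12.4. In centrosome against cytosol 26 were lower (median −2.54). In probe against no probe 4 of 26 tested histone genes were higher and 1 was lower. The histone share of counts was 0.261% ± 0.108 (SD, n = 3) in NES_Enrich and 0.0291% ± 0.0019 (SD, n = 3) in NES_Input. It was 0.0406% ± 0.00515 (SD, n = 3) in PCNT_Enrich, 0.022% ± 0.00598 (SD, n = 3) in PCNT_Input and 0.0349% ± 0.00661 (SD, n = 2) in PCNT_Control, so the share in PCNT_Enrich was near that without the probe. The genes were picked because they led the rises in the cytosol, so no test of them is given, and near-identical copies make single values uncertain.

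Of 10626 genes with at least 50 counts in every PCNT_Input library, 22 had no count in PCNT_Control replicate 2, 49 had none in replicate 3 and 3 had none in both. Each PCNT_Enrich library had counts of all 10626.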
